A study of Mus musculus with 16 samples.

How the data were processed

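Polyadenylated RNA was prepared from ventricles with Trizol and made into stranded libraries, per the labels' protocols, in 16 libraries of WT and JP2CR mice after sham surgery or TAC, 4 per group. Groups and replicate numbers were taken from the sample titles. The labels give 4 mice per group and do not tie each library to a named animal, so p-values measure the spread between these libraries. The submitters' processing notes name STAR 2.5.0b, bedtools 2.17.0, Cufflinks 2.2.1, DESeq2 1.6.3, Picard 1.128 and FastQC 1.0.0 and the mm10 build; the role of each tool, the annotation, the counter and its strand setting are not given in the sources used here. Genes that overlap, and members of near-identical families such as Ces1d, Acot1 and Serpinb1c, may share reads in ways that this leaves open.

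The values tested were whole-number read counts per gene symbol as deposited by the authors, not normalized. The same table carries the authors' own columns of log2 fold changes and adjusted p-values for the TAC effect in each genotype and for the sham libraries, deposited by the authors without a stated method. They are quoted only where the authors' deposited table is named; their unit in the third comparison is mixed, as some fields hold text in place of a number (other values). The authors' deposited table called 2855 genes higher and 2720 lower for TAC in WT, 5201 of them called here in the same direction, and 2354 and 2187 in JP2CR, with 4505 shared. Of 24421 entries, 27 had symbols turned into dates, 2 symbols stood on 2 entries, and 5817 had 0 counts in every library. No mitochondrially encoded genes were analysed here, and coordinates came from the RefSeq annotation of GRCm38.p6.

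Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr per group, scaled by TMM factors and fitted with a mean per group over all 16 libraries, and contrasts were tested by the quasi-likelihood F test. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called higher or lower. The 5 comparisons were TAC against sham in each genotype, the difference of these effects (the interaction), and JP2CR against WT in sham and in TAC. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM are counts relative to the TMM-scaled library total, and group values are means, with the SD where one is given.

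Gene lists were tested with camera of limma 3.58.1 on voom values at a preset correlation of 0.01, adjusted over the 27 lists with 5 or more tested members of 32 written down; an estimated correlation and fry were the alternatives. With an estimated correlation none of the lists was called in any comparison. In 13 of 135 tests of a list, none of them called, the median, the mean and the set test differed in sign. Counts "adjusted over the list alone" apply the Benjamini-Hochberg step to the edgeR p-values of the list's members only. The response score was the mean log2 CPM (prior count 2) over genes with an adjusted p under 0.05 and a log2 fold change of at least 1 in a fit of surgery alone, tested by permuting genotype within sham and within TAC.

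Genes were named by a fixed rule: 12 genes always (Jph2, Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Ryr2, Capn1, Capn2, Cast and Nnt); in each comparison of 2 groups the 6 highest and 6 lowest log2 fold changes among called genes with a mean log2 CPM of at least 1, no overlap of the groups and no predicted-gene symbol; in the interaction the 6 smallest p in each direction under the same expression and symbol limits; and up to 4 members of each list by smallest p. Some genes that this rule takes are not reported here. The groups, tests, lists, naming rule and the alternatives listed next were chosen before the data were examined. Alternatives were DESeq2 1.42.0, limma voom, size factors and upper-quartile factors, no filter and a stricter filter (1 CPM in 8 libraries), fits of only the groups compared, the replicate number as a block, an adjusted p under 0.01, a fold change of at least 1.5, and leaving out each library. Fits without the 3 libraries with Xist counts, without the 2 intermediate TAC libraries, without all 5 (each also with an estimated correlation in the set tests), and with marker means as covariates were added after the data were seen.

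The fits were tested on simulated counts drawn from the real means and library sizes with 1.5-, 2- and 4-fold changes. Libraries were drawn independently with the fitted spread of each gene. Only genes with a log2 of the mean CPM of at least 1 were changed. Shifts shared by many genes, such as those of sex or tissue content, and libraries close to each other were not simulated. For WT TAC against WT sham 76.1%, 95.5% and 98.5% of the changed genes were recovered with 11 false calls, and for the interaction 50.7%, 82.1% and 100.0% with 1 false call. Figures were drawn with matplotlib 3.10.9.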

Results

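Polyadenylated RNA from mouse ventricles was sequenced and counted per gene in 16 libraries, 4 in each of 4 groups. The mice were wildtype (WT) or carried JP2CR, a knock-in allele of Jph2 that lacks codons 563 to 568 and makes junctophilin-2 resistant to the protease calpain. Junctophilin-2 holds the transverse tubule membrane of the heart muscle cell close to the sarcoplasmic reticulum. At 9 to 10 weeks of age the mice had sham surgery or transverse aortic constriction (TAC), which narrows the aorta and loads the left ventricle with pressure, and ventricles were taken 5 weeks later. The question put by this design is whether the transcript response to pressure overload differs when junctophilin-2 resists calpain. Total counts per library ran from 9966782 to 16609732. A floor of 3 counts corresponded to 0.181 CPM in the deepest library and 0.301 CPM in the shallowest, which covers counting error only. Of 24421 entries in the table, 13522 passed the filter on low counts and were tested.

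Jph2 transcript levels were alike in the 4 groups. Mean CPM (± SD, n = 4) was 668 ± 37.6 in WT sham, 663 ± 24.5 in WT TAC, 686 ± 64.1 in JP2CR sham and 631 ± 33.3 in JP2CR TAC, and Jph2 was called in none of the 5 comparisons by edgeR (log2 fold change of JP2CR sham over WT sham 0.04 ± 0.06 SE, adjusted p = 0.921). Jph2 lies on chromosome 2 from 163336242 to 163398049 (GRCm38, the assembly also known as mm10). The deletion is in frame, so a count over the whole gene does not check the genotype of a library. Of 165 tested genes within 10 Mb of Jph2, 1 was called between the genotypes, against 97 called among the 12927 genes with a position (Fisher's exact test, 2-sided, p = 1). That gene was Serinc3, 0.34 ± 0.06 (log2) higher in JP2CR TAC than in WT TAC (adjusted p = 0.0218).

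Sex-linked transcripts and markers of atrial and adipose tissue set some libraries apart. All mice were labelled male, and 13 libraries had at most 0.266 CPM of Xist, the RNA that silences one X chromosome in female cells, with 179 to 237 CPM summed over the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y. JP2CR sham 3 and JP2CR sham 4 had 189 and 196 CPM of Xist and 0 counts of these 4 genes, and JP2CR TAC 4 had 141 CPM of Xist beside 118 CPM of the Y-linked genes. The mean log2 CPM of 12 atrial markers was 5.56 ± 0.44 (SD, n = 4) in WT sham, 2.72 ± 0.52 in WT TAC, 4.20 ± 2.04 in JP2CR sham and 3.87 ± 0.31 in JP2CR TAC. The mean of 10 adipocyte markers was 2.74 ± 1.31, -1.37 ± 0.54, 0.70 ± 1.99 and 0.80 ± 1.53 in the same order. The atrial mean was 1.16 in JP2CR sham 4 and 4.93 to 5.40 in JP2CR sham 1 to 3. In 2 TAC libraries, WT TAC 3 and JP2CR TAC 3, 98.8% and 97.6% of the genes that differed between replicates 1 and 2 of the group lay between these replicates. The same share was 89.6% for WT sham 3 and 21.3% for JP2CR sham 3. Counts of called genes, and of some gene lists, are also given without the 3 libraries with Xist and without the 2 intermediate TAC libraries. Without the 3 libraries with Xist, JP2CR sham 1 and 2 and JP2CR TAC 1 to 3 are the only JP2CR libraries left.

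**Figure D1:**
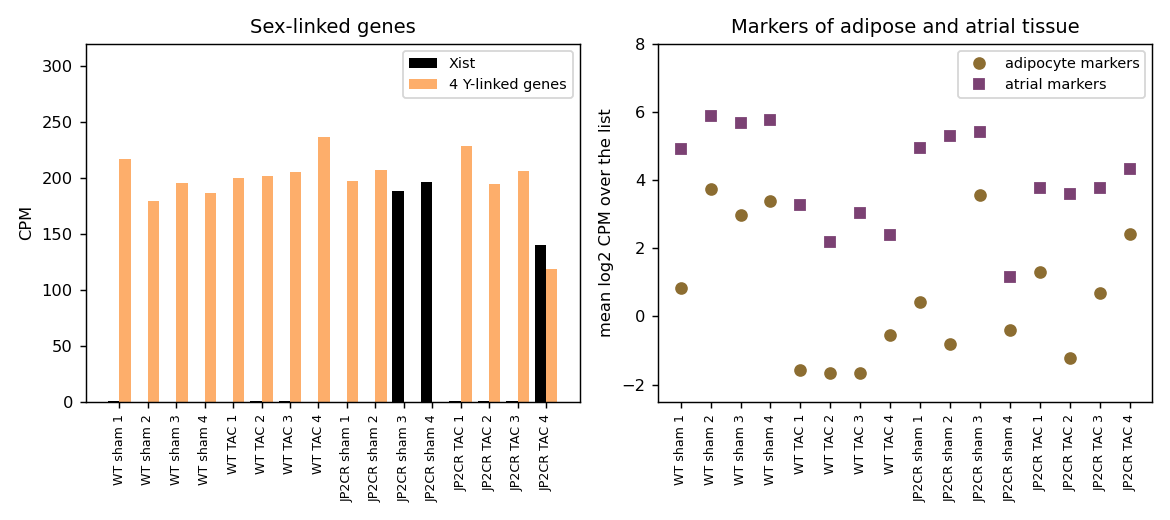
Sex-linked and tissue marker transcripts in each of the 16 libraries. Left, bars give CPM of Xist and the sum over 4 Y-linked genes. Right, points give the mean log2 CPM over 10 adipocyte and 12 atrial marker genes. Xist reached 141 to 196 CPM in 3 JP2CR libraries and at most 0.266 in the other 13. Both marker means were lower in every WT TAC library than in every WT sham library.

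In wildtype mice TAC raised genes of the fetal and load response and of the extracellular matrix, and lowered genes of fatty acid oxidation, the respiratory chain and ion channels and transporters. Myh7, the slow myosin heavy chain, went from 264 ± 17.8 to 7168 ± 970 CPM (SD, n = 4), 27.1-fold higher (log2 4.76 ± 0.25 SE, adjusted p = 7.35e-10). Skeletal actin Acta1 rose by 3.80 ± 0.41 (log2, adjusted p = 1.31e-06). The natriuretic peptide gene Nppb rose 7.91-fold, from 123 ± 7.93 to 977 ± 113 CPM (adjusted p = 1.94e-09). Myh6, the fast myosin heavy chain, and Atp2a2, the calcium pump of the sarcoplasmic reticulum, changed by -0.66 ± 0.10 and -0.64 ± 0.06 (log2; adjusted p = 3.07e-05 and 1.93e-07). In all, 2848 genes were called higher and 2817 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 519 and 510 changed by more than 2-fold.

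Among genes with no overlap between the libraries of the groups, large rises included those of the serpin gene Serpinb1c (68.7-fold), the cornified envelope gene Sprr1a (38.3-fold), the stress cytokine Gdf15 (30.1-fold), Myh7 and Zfp369 (25.8-fold). Serpinb1c and Sprr1a had 1 to 3 counts in each WT sham library, so their folds are imprecise. The largest falls were in genes abundant in adipose tissue. Ucp1, the uncoupling protein of brown fat, had 22.7 ± 17.2 CPM in WT sham and 0 counts in all 4 WT TAC libraries. Pck1 went from 26.7 to 0.182 CPM, the lipid droplet gene Plin1 from 10.7 to 0.0770, Car3 from 49.5 to 1.04, Cidec from 8.51 to 0.177 and the adipokine Adipoq from 7.94 to 0.194. With the adipocyte and atrial marker means as covariates, an alternative chosen after the data were seen, 1442 genes were called higher and 1452 lower, and the estimates for Ucp1 and Pck1 were 2.30 (adjusted p = 0.926) and 0.0866 (adjusted p = 0.994). Both genes are members of the adipocyte list whose mean was the covariate, so the loss of their calls was built into that fit.

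Of the 18 fetal and load genes, 17 rose and 1 fell in WT TAC (the same when adjusted over the list alone), with a median log2 fold change of 1.54. Xirp2 rose by 2.52 ± 0.09 and Enah, a regulator of actin filaments, by 1.44 ± 0.06. Of 34 matrix genes 32 rose, none fell and 2 were not called, and the list alone gave the same counts. Examples were Thbs4 (4.24 ± 0.29), the latent TGF-beta binding protein Ltbp2 (3.71 ± 0.22), the metalloproteinase inhibitor Timp1 (2.35 ± 0.14) and Tgfb2 (1.67 ± 0.11). Both lists stood above other genes in the set test with a preset correlation (adjusted p = 4.19e-12 and 1.48e-18). Both had an adjusted p = 0.0695 with an estimated correlation. Cell cycle genes rose in 22 of 25 cases, with Mki67 at 1.73 ± 0.21 and Bub1 at 2.39 ± 0.37. Cenpf fell by 2.16 (log2), and 23 rose and 1 fell adjusted over the list alone. That list had an adjusted p = 1.39e-05, and an adjusted p = 0.365 with an estimated correlation.

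Metabolic lists other than glycolysis moved down together in WT TAC. Of 29 tested fatty acid oxidation genes 26 fell and none rose, led by Acaa2 (-1.34 ± 0.07), Hadh (-0.94 ± 0.06), Eci1 (-0.82 ± 0.06) and Decr1 (-0.81 ± 0.06). All 35 respiratory chain and ATP synthase genes fell (median -0.35; Cox7a1 -0.77 ± 0.06, Sdhc -0.59 ± 0.05), as did 16 of 17 genes of branched-chain amino acid catabolism (Bckdhb -0.81 ± 0.06, Mccc2 -0.74 ± 0.06) and 14 of 15 of the tricarboxylic acid cycle (Suclg1 -0.54 ± 0.04, Cs -0.45 ± 0.04). Adjusted over the list alone, the numbers that fell were 26, 35, 16 and 15. Preset-correlation adjusted p values were 4.11e-17, 2.53e-19, 5.28e-11 and 1.22e-09. The adjusted p was 0.0745 for the respiratory chain and 0.0695 for the other lists with an estimated correlation. Nnt, the mitochondrial transhydrogenase, changed by -0.44 ± 0.06 (adjusted p = 5.95e-06). Of 18 glycolysis genes 7 rose and 6 fell over all genes and over the list alone (Pfkp 1.20 ± 0.07, Ldhb -0.54 ± 0.05), and the list was not called (adjusted p = 0.876).

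Among 22 ion channel and transporter genes 16 fell and 1 rose (over the list alone likewise), including the T-type calcium channel Cacna1h (-2.36 ± 0.20), the potassium channel Kcnd2 (-1.33 ± 0.17), its partner Kcnip2 (-0.62 ± 0.07) and Kcnk3 (-0.48 ± 0.06). The set test gave an adjusted p = 1.98e-06, and an adjusted p = 0.0695 with an estimated correlation. Dyad and calcium handling genes moved both ways, 5 up and 7 down of 25 (6 and 7 adjusted over the list alone), and the list was not called (adjusted p = 0.677). The calcium binding protein Hrc fell by 0.97 and phospholamban Pln by 0.50, while Ehd4 rose by 0.80. Sln, which is on this list and on the atrial marker list, went from 188 to 9.34 CPM. The release channel Ryr2 was not called (-0.01 ± 0.07, adjusted p = 0.918). In the calpain list, 2 of 10 genes rose and 1 fell, also over the list alone. These were the inhibitor calpastatin, Cast (0.41 ± 0.06), Capn2 (0.16 ± 0.05) and Capn1 (-0.33 ± 0.07), and the list had an adjusted p = 0.991. Sarcomere genes rose in 11 and fell in 5 of 20 cases (the same over the list alone; Myot 1.61 ± 0.13, Ttn 0.82 ± 0.07, Tnni3 -0.77 ± 0.06), with an adjusted p = 0.152.

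Stress and interferon lists held genes that rose and genes that fell in WT TAC. Of 22 interferon response genes 11 rose and 1 fell (12 and 1 adjusted over the list alone), with Ifit2 at 0.96 ± 0.07. Of 13 oxidative stress genes 8 rose and 1 fell (9 and 1), with Nqo1 at 0.51 ± 0.05 and Sod2 at -0.50 ± 0.05. Their set tests gave adjusted p = 0.00381 and 0.00612, and adjusted p = 0.301 and 0.195 with an estimated correlation. Of 21 unfolded protein response genes 2 rose and 9 fell, also over the list alone (Hspa5 -0.58 ± 0.06, Canx -0.37 ± 0.06, Atf4 0.58 ± 0.10; adjusted p = 0.0374, and adjusted p = 0.509 with an estimated correlation). Heat shock genes (3 rose and 2 fell of 11, adjusted p = 0.659), immediate early genes (5 and 4 of 19, adjusted p = 0.978) and clock genes (1 and 2 of 16, adjusted p = 0.334) were not called as lists, and their counts over the list alone were the same. Fosb, an immediate early transcription factor, fell by 3.27 and the clock output gene Hlf by 1.45. Immediate early genes rose and fell in 3 and 3 cases without the 2 intermediate TAC libraries, in 3 and 2 without WT sham 2 and in 2 and 3 without WT sham 3 or WT sham 4. Clock genes did so in 3 and 3 cases without the 3 libraries with Xist counts, in 2 and 5 without WT TAC 1 and in 0 and 1 without WT TAC 2.

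Markers of other cell types moved apart in WT TAC. Macrophage markers rose in 14 and fell in 1 of 19 cases (14 and 2 adjusted over the list alone; C1qa 0.55 ± 0.09, Ccr2 1.20 ± 0.23; adjusted p = 0.00255, and adjusted p = 0.320 with an estimated correlation). None of 16 endothelial markers was called by edgeR over all genes or over the list alone (median 0.02). Without the 3 libraries with Xist counts 3 rose and 1 fell, and without any one of WT sham 1, WT TAC 1, WT TAC 2 or WT TAC 4 there was 1 that rose. In contrast, 4 of 14 fibroblast markers rose and 3 fell and 1 of 12 smooth muscle and pericyte markers rose and 7 fell, with the same counts over the list alone. These 3 lists had adjusted p = 0.860, 0.557 and 0.0606, and the last had adjusted p = 0.0428 without the 3 libraries with Xist counts and 0.0479 without the 2 intermediate ones. With an estimated correlation those were adjusted p = 0.596 and 0.538. Atrial markers fell in 11 of 12 cases (Stard10 -3.18 ± 0.30, Kcnj3 -2.07 ± 0.13, Sln -4.35 ± 0.80), nerve and Schwann cell markers in 6 of 7 (Kcna1 -2.77 ± 0.24, Dbh -2.37 ± 0.31), adipocyte markers in 9 of 10 and skeletal muscle markers in 3 of 5 (Atp2a1 -4.19 ± 0.45). Over the list alone 11, 7, 9 and 3 fell, and 1 skeletal muscle marker rose. Adjusted p values were 0.000483, 0.000238, 0.00954 and 0.152, and the adjusted p with an estimated correlation was 0.365, 0.0695, 0.509 and 0.509. The adipocyte median was -6.15, or -5.56 with Retn and Ucp1, both at 0 in WT TAC, set to a floor of 3 counts over the group. Of 8 mesothelial markers 1 rose and 1 fell (adjusted p = 0.207), also over the list alone, and 6 fell without WT TAC 1.

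**Figure D2:**
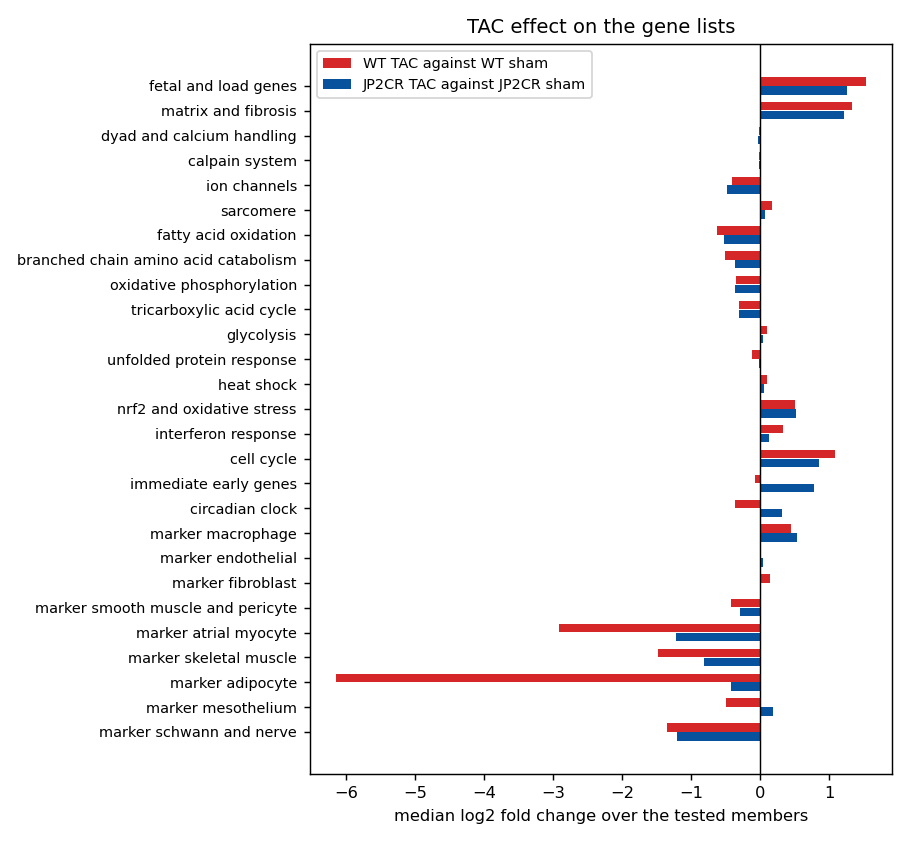
Median log2 fold change (TAC over sham) over the tested members of each of 27 gene lists, as bars for WT and for JP2CR. The fetal and load list stood at 1.54 and 1.26 and the fatty acid oxidation list at -0.63 and -0.52; the WT adipocyte bar at -6.15 includes 2 genes at 0 counts in WT TAC.

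In JP2CR mice TAC also raised the fetal and matrix genes. It lowered genes of fatty acid oxidation, the respiratory chain, branched-chain amino acid catabolism and the tricarboxylic acid cycle. Of 18 glycolysis genes 4 rose and 6 fell (median 0.05). Myh7 rose 21.2-fold, from 214 ± 86.5 to 4563 ± 607 CPM (SD, n = 4; log2 4.41 ± 0.25 SE, adjusted p = 1.70e-09), Acta1 12.3-fold (adjusted p = 2.86e-06) and Nppb 3.63-fold, from 193 ± 60.9 to 703 ± 97.1 CPM (adjusted p = 2.67e-07). Myh6 and Atp2a2 changed by -0.70 ± 0.10 and -0.57 ± 0.06 (adjusted p = 2.11e-05 and 1.07e-06), Cast by 0.38 ± 0.06, Capn2 by 0.26 ± 0.05 and Capn1 by -0.25 ± 0.07. The atrial natriuretic peptide gene Nppa, called in WT TAC (1.33 ± 0.52, adjusted p = 0.0473), had an estimate of 1.19 ± 0.52 (adjusted p = 0.0736). Nppa had 149 CPM in JP2CR sham 4 and 1295 to 3890 in JP2CR sham 1 to 3. The atrial marker Myl7 had 0.941 CPM in JP2CR sham 4 and 299 to 803 in JP2CR sham 1 to 3. Mean Myl7 was 632 CPM in WT sham and 29.0 in WT TAC. The Nppa estimates may thus reflect atrial content as well as TAC, which was not tested. The Nppa difference between the TAC effects was -0.14 ± 0.72 (edgeR interaction test, adjusted p = 0.970). In all, 2800 genes were called higher and 2805 lower, of which 531 and 294 changed by more than 2-fold.

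Large rises without overlap between groups included Sprr1a (43.9-fold), Myh7, the immunoglobulin joining chain Jchain (19.5-fold, 18.5 ± 19.7 CPM in JP2CR TAC), Serpinb1c (17.7-fold) and Ltbp2 (13.2-fold). Sprr1a had 0 to 5 counts in the JP2CR sham libraries, and Serpinb1c had 15 in JP2CR sham 3 and 1 in each of the others, so their folds are imprecise. Jchain had 606 and 275 counts in JP2CR TAC 1 and 3, against 50 and 52 in JP2CR TAC 2 and 4. The largest falls were those of the kinase gene Sbk2 (-2.66 ± 0.32), the carboxylesterase Ces1d (-2.61 ± 0.33), Lingo3 (-2.52 ± 0.32), the collagen gene Col6a6 (-2.36 ± 0.21), the chloride channel Clcn1 (-2.33 ± 0.12) and the acyl-CoA thioesterase Acot1 (-2.26 ± 0.35). Fetal and load genes rose in 16 and fell in 1 of 18 cases (17 and 1 adjusted over the list alone), matrix genes rose in 31 of 34 and cell cycle genes rose in 16 and fell in 1 of 25 (31 of 34, and 21 and 1, over the list alone). Cell cycle genes rose in 4 and fell in 1 case without the 3 libraries with Xist counts, in 2 and 1 without these and the 2 intermediate ones, and in 10 and 1 without JP2CR TAC 2. Fatty acid oxidation genes fell in 23 of 29 cases (24 fell and 1 rose over the list alone), branched-chain genes in 16 of 17, respiratory chain genes in 35 of 35, tricarboxylic acid cycle genes in 13 of 15 (14 over the list alone) and ion channel genes in 17 of 22 (18). Examples were Xirp2 (2.08 ± 0.09), Timp1 (2.74 ± 0.14), Acaa2 (-0.99 ± 0.07), Bckdhb (-0.90 ± 0.06) and Kcnip2 (-0.73 ± 0.07). These 8 lists were called with a preset correlation, at adjusted p = 1.50e-10, 3.34e-18, 6.07e-05, 6.43e-14, 2.11e-10, 1.64e-20, 2.55e-09 and 4.21e-07. With an estimated correlation the adjusted p was 0.506 for the cell cycle, 0.0837 for ion channels, 0.0914 for fatty acid oxidation and 0.0867 for the other 5.

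Of 19 immediate early genes 13 rose and none fell in JP2CR TAC, over all genes and over the list alone, among them Junb (1.89 ± 0.26), Egr2 (3.50 ± 0.52), Nr4a3 (1.79 ± 0.33) and Zfp36 (1.21 ± 0.23). The list had an adjusted p = 0.000782, and an adjusted p = 0.506 with an estimated correlation. Macrophage markers rose in 14 of 19 cases (16 over the list alone; Cd14 0.94 ± 0.13, Lyz2 0.58 ± 0.08), oxidative stress genes rose in 9 and fell in 1 of 13 (the same over the list alone; Mt2 2.63 ± 0.37, Nqo1 0.53 ± 0.05), and nerve and Schwann cell markers fell in 5 of 7, also over the list alone (Dbh -1.96 ± 0.30). Their adjusted p values were 2.71e-06, 0.000693 and 0.00176, with an adjusted p = 0.0914 for each with an estimated correlation. None of 10 adipocyte markers was called by edgeR, over all genes or over the list alone (median -0.42, adjusted p = 0.976 in a set test that pointed upward), and 5 of 12 atrial markers fell (adjusted p = 0.365). The adipocyte values rested on single libraries. Without JP2CR sham 3 the median was 2.48 and 5 markers were called higher, without JP2CR TAC 4 it was -1.02 with 2 lower, and without JP2CR TAC 2 it was -0.06 with 1 higher. Without the 3 libraries with Xist counts it was 0.83 with 2 higher. Atrial markers fell in 8 cases in that fit (list adjusted p = 0.000517, and adjusted p = 0.101 with an estimated correlation), in 10 without JP2CR sham 4 and in 3 without any one of JP2CR sham 2 and JP2CR TAC 1, 2 and 3 or without the 2 intermediate libraries. Clock genes, of which 1 of 16 rose, rose in 6 and fell in 2 cases without the libraries with Xist, in 2 and 2 without JP2CR sham 3 and in 3 and 0 without JP2CR sham 4. Heat shock genes, 3 and 3 of 11, did so in 6 and 2 cases without the libraries with Xist. Interferon response genes rose in 5 and fell in 1 of 22 cases, likewise over the list alone (adjusted p = 0.359). Dyad and calcium handling genes rose in 6 and fell in 6 of 25, and calpain genes rose in 2 and fell in 2 of 10, with the same counts over the list alone and no call as lists (adjusted p = 0.737 and 0.976).

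The TAC effects of the 2 genotypes, which share no library, were correlated across the 13522 tested genes (Pearson r = 0.774, Spearman rho = 0.781; genes are not independent replicates, so no p is given). Of the 2848 genes called higher in WT and the 2800 in JP2CR, 2080 were shared, where independent lists would share 590. Among lower genes 1992 were shared, against 584, and 20 genes were called in opposite directions. Leaving out JP2CR sham 3 gave a correlation of 0.666.

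**Figure D3:**
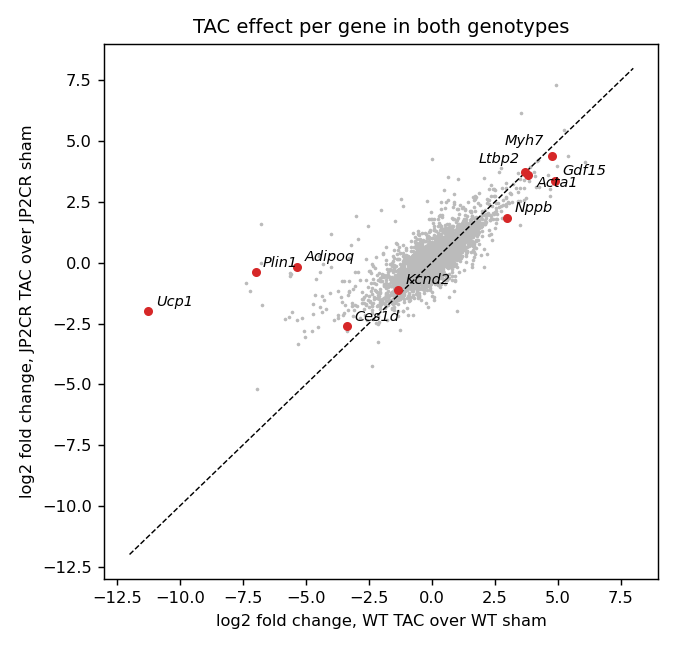
Each point is a gene, with its log2 fold change of TAC over sham in WT on the horizontal axis and in JP2CR on the vertical axis; the dashed line marks equal effects. Points lie along the line (r = 0.774) except for a group lower in WT, among them Ucp1, Plin1 and Adipoq; the plotted WT value of Ucp1 is a fitted one, as it had 0 counts in WT TAC.

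The test of the difference between the TAC effects (JP2CR minus WT) called 16 genes, 12 with a positive and 4 with a negative difference. The serum and glucocorticoid regulated kinase gene Sgk1, on chromosome 10 from 21882184 to 21999903, had the smallest p: 96.4 ± 5.18 CPM in WT sham and 74.6 ± 7.81 in WT TAC against 57.4 ± 4.16 in JP2CR sham and 101 ± 21.8 in JP2CR TAC (SD, n = 4; difference 1.19 ± 0.17 log2 SE, adjusted p = 0.0128). Beside it, positive differences were called for the mitochondrial pyruvate carrier Mpc1 (0.47 ± 0.07), Rgs2, a regulator of G protein signalling (1.35 ± 0.22), the matrix gene Efemp1 (1.31 ± 0.22) and the antigen presentation genes H2-Eb1 (0.71 ± 0.12) and H2-K1 (0.46 ± 0.08). Negative differences were those of the angiogenic factor Vegfa (-0.59 ± 0.10), Gpr157 (-0.46 ± 0.08), the phospholipase gene Plcd3 (-0.73 ± 0.12) and the kinase gene Tnik (-0.56 ± 0.10). Vegfa stood at 428 and 499 CPM in WT sham and TAC and at 520 and 404 in JP2CR sham and TAC.

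Classical load genes did not pass this test. Nppb had a difference of -1.12 ± 0.23 (adjusted p = 0.0549), Myh7 of -0.36 ± 0.31 (adjusted p = 0.754), Acta1 of -0.18 ± 0.52 (adjusted p = 0.941) and Atp2a2 of 0.07 ± 0.08 (adjusted p = 0.842). As a list the fetal and load genes lay below other genes (median -0.26, adjusted p = 0.000652, and adjusted p = 0.395 with an estimated correlation), with no member called by edgeR over all genes and 4 lower adjusted over the list alone. Immediate early genes lay above (median 1.02, adjusted p = 3.69e-08, and adjusted p = 0.335 with an estimated correlation), with 0 called and 10 higher over the list alone, and clock genes likewise (median 0.54, adjusted p = 0.000652, and adjusted p = 0.335 with an estimated correlation), with 0 called and 0 over the list alone. Values were 3.20 ± 0.67 for Fos (adjusted p = 0.0555), 1.59 ± 0.31 for Zfp36 (adjusted p = 0.0549) and 1.38 ± 0.63 for Per1 (adjusted p = 0.454). Fatty acid oxidation genes had a median of 0.12 (2 higher over the list alone, Acaa2 0.35 ± 0.09) and interferon genes one of -0.21 (1 higher and 1 lower over the list alone), at adjusted p = 2.71e-06 and 0.000996 and adjusted p = 0.395 and 0.335 with an estimated correlation. Adipocyte markers (median 5.14; 7 higher over the list alone) and atrial markers (median 1.41; 5 higher over the list alone, Kcnj3 0.88 ± 0.18) gave adjusted p = 6.27e-06 and 1.90e-06, and adjusted p = 0.355 and 0.335 with an estimated correlation. Among 19 macrophage markers only Cd163 was called (0.94 ± 0.17, adjusted p = 0.0398; list adjusted p = 0.0144, and adjusted p = 0.473 with an estimated correlation). The other 7 called lists had an adjusted p of 0.335 to 0.604 with an estimated correlation, and fry called 0 of the 27 lists in one direction. Its test of change in both directions at once called the interferon and macrophage lists (adjusted p = 0.00143 and 0.0362). Neither the dyad list (median 0.00, adjusted p = 0.890) nor the calpain list (median -0.02, adjusted p = 0.890) was called, and edgeR called 0 of their members over all genes and over the list alone.

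The number of interaction calls depended on single libraries. Counts higher and lower were 93 and 27 without JP2CR sham 3, 38 and 15 without JP2CR sham 4, 51 and 13 without JP2CR TAC 1 and 27 and 19 without WT TAC 1. They were 2 and 0 without any one of WT sham 3, WT sham 4, WT TAC 2, WT TAC 3, JP2CR sham 1, JP2CR TAC 3 or JP2CR TAC 4, 4 and 0 without JP2CR sham 2, and 8 and 2 without WT sham 1. Without the 3 libraries with Xist counts edgeR called 213 and 159 genes, all 16 above among them, and the Nppb difference was -1.01 ± 0.13 (adjusted p = 0.00115). That fit rests on JP2CR sham 1 and 2 alone for the JP2CR sham group, and its counts were not tested by splits. Without the 2 intermediate TAC libraries edgeR called 0 and 0, with 1049 genes at an unadjusted p under 0.05, and without all 5 it called 42 and 17. Lists changed as well. Without the libraries with Xist 6 immediate early genes, 5 adipocyte markers and 5 atrial markers were called higher and 3 fetal and load genes lower, and the interferon list was not called (adjusted p = 0.209). Immediate early genes were higher in 6 cases without JP2CR sham 3 and in 8 without JP2CR TAC 1, and in 1 without WT sham 1, WT TAC 1 or JP2CR sham 4. Adipocyte markers were higher in 6 cases without JP2CR sham 3, with a median of 7.94, and in 1 without JP2CR TAC 2. Atrial markers were higher in 1 case without any one of WT TAC 1, JP2CR sham 3, JP2CR sham 4 or JP2CR TAC 2. Fetal and load genes were lower in 2 cases without WT TAC 1 or JP2CR sham 4 and in 1 without JP2CR sham 3, where the median was -0.11. Among single omissions a macrophage marker was called without JP2CR sham 3, JP2CR sham 4, JP2CR TAC 1 or WT TAC 1, and 0 were called without any one of the other 12 libraries. With all libraries 1395 genes had an unadjusted p under 0.05, and DESeq2 called 91 and 41.

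**Figure D4:**
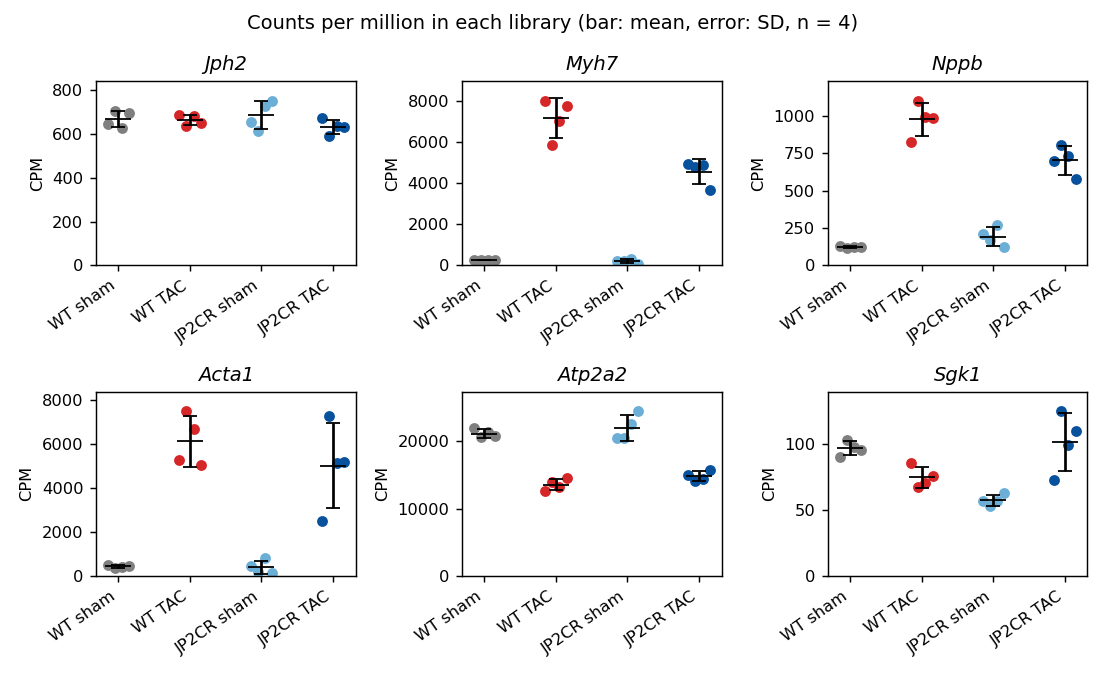
CPM of 6 genes in each library by group; horizontal bars give the mean and error bars the SD (n = 4). Jph2 lies between 589 and 750 CPM in all libraries, Myh7 and Nppb are higher in every TAC than in every sham library of their genotype, and mean Sgk1 is 57.4 CPM in JP2CR sham and 96.4 in WT sham.

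A score per library summarised the response over genes selected on surgery alone. Over 515 genes higher in TAC the mean log2 CPM rose by 1.51 in WT and 1.54 in JP2CR, a difference of 0.03 (exact permutation test, 2-sided, p = 0.802; adjusted over the 2 scores, 0.802). Over 380 genes lower in TAC it changed by -1.82 in WT and -1.10 in JP2CR, a difference of 0.72 (exact permutation test over 4900 arrangements, 2-sided, p = 0.00122; adjusted p = 0.00245). Group means of this second score were 2.87 ± 0.15 in WT sham, 1.06 ± 0.02 in WT TAC, 2.51 ± 0.27 in JP2CR sham and 1.40 ± 0.25 in JP2CR TAC (SD, n = 4). With the adipocyte and atrial marker means as covariates, chosen after the data were seen, the difference was 0.14 ± 0.11 (SE), within 2 SE of 0. Members of these marker lists were not removed from the score, so part of this drop may be built into the fit.

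Without pressure overload, 13 genes were lower in JP2CR than in WT and none was called higher. Sik1, a kinase gene induced by cyclic AMP signalling, stood at 46.2 ± 3.89 CPM in JP2CR sham and 102 ± 9.59 in WT sham (SD, n = 4; log2 -1.14 ± 0.17 SE, adjusted p = 0.0122). The transcription factor genes Klf2 (-0.92 ± 0.11, adjusted p = 0.00206), Fosl2 (-0.73 ± 0.10, adjusted p = 0.00356) and Nr4a2 (-1.35 ± 0.22, adjusted p = 0.0199) were lower as well, as were Sgk1 (-0.75 ± 0.12, adjusted p = 0.0160) and Enc1 (-0.58 ± 0.10, adjusted p = 0.0346). Beyond the rule for named genes, and chosen after their values were seen, the antigen presentation genes H2-K1 (-0.35 ± 0.06) and B2m (-0.43 ± 0.07) and the interferon-inducible GTPase genes Igtp (-0.57 ± 0.10) and Irgm2 (-0.43 ± 0.08) were also called lower. At an unadjusted p under 0.05 edgeR listed 1078 genes; DESeq2 called 13 higher and 39 lower and limma voom 0 and 18. The authors' deposited table listed 15 genes higher and 47 lower for this comparison, and it held all 13 genes called here, in the same direction.

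Immediate early genes lay below other genes in JP2CR sham (median -0.71; 1 of 19 called lower and 11 lower adjusted over the list alone), with an adjusted p = 2.02e-09, and an adjusted p = 0.351 with an estimated correlation. Clock genes had a median of -0.21 (0 called by edgeR and 0 over the list alone; adjusted p = 0.00628, and adjusted p = 0.504 with an estimated correlation). Interferon response genes lay above (median 0.23; 1 of 22 called lower and none higher, 5 higher and 1 lower over the list alone; Rsad2 0.48 ± 0.10), with an adjusted p = 2.41e-05, and an adjusted p = 0.351 with an estimated correlation. Cell cycle genes had a median of 0.30 (3 higher over the list alone), adipocyte markers of -1.04 (1 lower over the list alone) and atrial markers of -0.45 (0 over the list alone), at adjusted p = 3.84e-05, 3.84e-05 and 2.41e-05. With an estimated correlation the adjusted p was 0.527, 0.504 and 0.504. Fatty acid oxidation genes had a median of -0.06 (none called by edgeR over all genes or over the list alone; adjusted p = 0.000470, and adjusted p = 0.598 with an estimated correlation). The other 4 called lists were branched-chain and skeletal muscle genes (lower) and endothelial and unfolded protein response genes (higher), with an adjusted p of 0.351 to 0.527 with an estimated correlation. Fetal and load genes were not called as a list (adjusted p = 0.571), and Nppb stood at 0.65 ± 0.16 (adjusted p = 0.195).

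Single libraries moved the sham counts: 27 genes were lower without JP2CR sham 3, 8 without JP2CR sham 2, 7 without WT sham 2 and 5 without WT sham 3, and 0 to 5 were higher (5 without JP2CR sham 4). Without the 3 libraries with Xist counts 20 were higher and 44 lower, 10 of the 13 among them, and without the 2 intermediate TAC libraries, which enter through the shared spread, 0 and 6. Immediate early genes were lower in 5 cases without the libraries with Xist, in 7 without JP2CR sham 3 and in 2 without WT sham 1. The adipocyte median was -3.25 without the libraries with Xist and -3.51 without JP2CR sham 3, each with 1 marker lower. The interferon, endothelial, branched-chain and unfolded protein response lists were not called without the libraries with Xist (adjusted p = 0.0855, 0.192, 0.225 and 0.656). In the same fit the heat shock and oxidative stress lists, not called with all libraries (adjusted p = 0.571 and 0.912, upward), had adjusted p = 0.000934 and 0.0384 downward, and adjusted p = 0.475 and 0.435 with an estimated correlation.

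Under pressure overload 88 genes were called between the genotypes, 49 higher and 39 lower in JP2CR TAC, with Cd163 and Fkbp5 among the higher and Xirp2 and Rcan1 among the lower ones. The scavenger receptor gene Cd163, a macrophage marker, was 1.07 ± 0.12 higher (log2; adjusted p = 0.000579), the chemokine gene Ccl6 went from 7.35 ± 1.61 to 23.3 ± 11.5 CPM (SD, n = 4; adjusted p = 0.0169) and Fkbp5, an immunophilin induced by glucocorticoids, from 27.3 ± 1.87 to 75.5 ± 10.1 CPM (adjusted p = 0.0313). Other large rises were Timp4 (1.29 ± 0.26), Map3k6 (1.24 ± 0.27), Slc10a6 (1.19 ± 0.26) and Ifi205 (1.15 ± 0.21). Akr1c19 (-0.87 ± 0.18), the splicing regulator Srrm4 (-0.75 ± 0.15), Plcd3 (-0.70 ± 0.09, adjusted p = 0.00102), Zfp608 (-0.61 ± 0.13), the ventricular transcription factor Irx4 (-0.58 ± 0.09) and Arl4c (-0.54 ± 0.11) were lower.

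Of the 18 fetal and load genes 3 were lower in JP2CR TAC and none was called higher (5 lower adjusted over the list alone): Xirp2 (-0.53 ± 0.09), the calcineurin regulator Rcan1 (-1.02 ± 0.21) and Enah (-0.26 ± 0.05). Myh7 stood at -0.65 ± 0.22 (adjusted p = 0.189) and Nppb at -0.47 ± 0.16 (adjusted p = 0.194). The list had an adjusted p = 5.00e-05, and an adjusted p = 0.463 with an estimated correlation. Macrophage markers were higher in 2 of 19 cases, Cd163 and Lyve1 (0.92 ± 0.17), and in 6 over the list alone (adjusted p = 4.84e-06, and adjusted p = 0.254 with an estimated correlation). Unfolded protein response genes had a median of 0.16, with 0 called by edgeR and 6 higher over the list alone (Manf 0.24 ± 0.06; adjusted p = 1.38e-06, and adjusted p = 0.254 with an estimated correlation). Of 16 endothelial markers Esam was called (0.31 ± 0.06; 6 higher and 1 lower over the list alone; adjusted p = 0.00667, and adjusted p = 0.254 with an estimated correlation). Matrix genes had a median of -0.11, with 0 called and 6 lower over the list alone (Thbs4 -1.03 ± 0.23, adjusted p = 0.0543; list adjusted p = 0.00667, and adjusted p = 0.657 with an estimated correlation). Adipocyte markers stood at a median of 4.43 (4.42 with the genes at 0 set to their floor), with Retn called at 1.24 ± 0.852 CPM against 0 counts in WT TAC and 5 members higher over the list alone, and atrial markers at 0.81, with Kcnj3 called (0.68 ± 0.13), also over the list alone. These 2 lists had adjusted p = 0.00667 and 0.00390, and adjusted p = 0.535 each with an estimated correlation. The other 10 called lists had an adjusted p of 0.483 to 0.665 with an estimated correlation.

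Without the 3 libraries with Xist counts 228 genes were higher and 150 lower, without the 2 intermediate TAC libraries 2 and 2, and without all 5 libraries 14 and 5. Among single libraries, counts higher and lower were 6 and 4 without WT TAC 2, 5 and 3 without WT TAC 3, 7 and 5 without WT TAC 4, 10 and 6 without JP2CR TAC 3, 13 and 11 without JP2CR TAC 4, 63 and 62 without WT TAC 1 and 62 and 23 without JP2CR TAC 1. Fetal and load genes were lower in 5 cases without the libraries with Xist, in 0 without the 2 intermediate libraries or any one of WT TAC 2, 3 and 4, and in 1 without JP2CR TAC 3 or JP2CR TAC 4. Macrophage and endothelial markers were higher in 4 cases each, atrial markers in 5 and adipocyte markers in 2 without the libraries with Xist. The matrix and adipocyte lists were not called there (adjusted p = 0.151 and 0.0625). Matrix genes were lower in 3 cases without WT TAC 1 and in 1 without JP2CR TAC 2, and 1 was higher and 2 lower without the libraries with Xist. Over the 8 single omissions, the 1 call each of endothelial, adipocyte and atrial markers was lost in 6, 7 and 6 cases, and 1 macrophage marker was left in 5. The adipocyte median was 3.10 without JP2CR TAC 4 and 5.86 without WT TAC 4.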

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

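The tests of Xist against read errors and of a mixed JP2CR TAC 4 library, of mixture and of chance for the intermediate libraries, of counts without these, and of the score without marker-tracking genes or without the libraries with Xist were chosen after the result was seen. Of 240 groups of 4 libraries examined for a sample far from the others, 28 held one. Chance gives about 1 in 20 groups for normal, independent values. Most items were genes named from these same data, and some vary together, as the adipose genes do. The 28 are therefore not separate trials to set against that rate.

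JP2CR sham 3 stood apart in adipose genes: Ucp1 had 35.5 CPM there and at most 0.0713 in the other libraries of the group, Pck1 54.0 against 1.71, Plin1 10.8 against 0.856, Car3 103 against 10.6, Cidec 18.7 against 1.28 and Adipoq 14.7 against 1.21. It was also highest in Ces1d (321 CPM, next 229) and Serpinb1c (0.925, next 0.105). JP2CR TAC 4 was highest in its group in Ucp1 (9.02 CPM, others 0), Pck1 (23.9, next 1.95), Ces1d (87.8, next 26.1), Clcn1 (6.75, next 4.60), Myh6 (27619, next 24425) and Nnt (1176, next 1091), and lowest in Myh7 (3655, next 4808). In WT TAC 4, Pck1 had 0.642 CPM, Car3 3.77 and Cidec 0.482, against at most 0.0838, 0.168 and 0.0838 in the rest of the group, and Ryr2 had 2455 CPM (next 2196). Single values far from their group were also seen for Rgs2 in JP2CR sham 4 (51.0 CPM, next 33.8), H2-Eb1 in WT sham 4 (60.6, next 55.8), H2-K1 in JP2CR TAC 2 (187, next 205), Gpr157 and Enc1 in JP2CR TAC 1 (65.3, next 71.1; 15.04, next 18.7), Srrm4 in WT sham 1 (32.3, next 30.6) and Xist in WT sham 1 (0.0839 CPM, 1 count, others 0). In JP2CR TAC 4, Xist had 141 CPM (next 0.0807) and Ddx3y 54.8 (next 94.1).

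The TAC effect differed between the genotypes, by the interaction test, in Sgk1 (1.19), Mpc1 (0.47), Rgs2 (1.35), Efemp1 (1.31), H2-Eb1 (0.71), H2-K1 (0.46), Vegfa (-0.59), Gpr157 (-0.46), Plcd3 (-0.73) and Tnik (-0.56), all as log2 JP2CR minus WT. Of 100 splits of the libraries, out of 2450 possible, only the real one gave 16 calls or more, and the highest other gave 9. Chance is thus unlikely for this count, but not excluded, if the 16 libraries are independent. The count was 0 without WT TAC 3 and JP2CR TAC 3, the intermediate libraries, and 2 without either one. For the TAC effects 1 of 35 splits reached the real count (5665 in WT, highest other 0, and 5605 in JP2CR, highest other 208). This is the lowest share that 35 splits can give, and the shares were not adjusted over the comparisons. Both real counts lay far above the others, so chance is unlikely there. For JP2CR TAC against WT TAC 1 of 35 splits reached the real count (88, highest other 16), again the lowest possible share. That does not exclude chance, even if the libraries are independent, and the count was 4 without both intermediate libraries. For the 13 genes of JP2CR sham against WT sham, 2 of 35 splits were as large and chance cannot be excluded. The other split, with 48 calls, set WT sham 1 and JP2CR sham 1, 2 and 4 against WT sham 2, 3 and 4 and JP2CR sham 3, which are the libraries with the lower and the higher adipocyte marker means.

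The first pattern is Xist in 3 libraries labelled male. Reads wrongly assigned to Xist in male mice are argued against by the summed Y-linked CPM, which was 0% of the mean of the 13 other libraries in JP2CR sham 3 and 4. X-linked genes that escape inactivation had a median log2 ratio of 0.64 in these 2 libraries over JP2CR sham 1 and 2, above the highest value of 0.12 among splits of WT sham, which is consistent with female mice. JP2CR TAC 4 had 56.4% of the Y-linked CPM of JP2CR TAC 1 to 3 beside Xist, consistent with RNA of a male and a female mouse in one library. In JP2CR sham 3 and 4 the Y-linked genes had 0 counts, against 2773 and 2268 in JP2CR sham 1 and 2. This argues against RNA of a male mouse mixed into JP2CR sham 3 and 4. How female RNA came into libraries labelled male stays open, as does the step at which JP2CR TAC 4 was mixed, if it was. The counts of the interaction with and without the 3 libraries differ as given above.

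The second pattern is that WT TAC 3 and JP2CR TAC 3 lay between replicates 1 and 2 of their groups. The lower of the 2 shares of genes lying between was 97.6%, above 89.6%, the highest of 46 other combinations. The libraries were picked by this share, so it does not test whether they were mixed from replicates 1 and 2. The 89.6% was that of WT sham 3, also between replicates 1 and 2, while JP2CR sham 3 had 21.3%. As mixtures of replicates 1 and 2, with a best weight of 50% each, WT TAC 3 and JP2CR TAC 3 had noise indices of 1.29 and 1.42. An index of 1 stands for counting noise alone, which thus did not account for their distance from a mixture. WT sham 3 had 1.45, with a best weight of 80% for WT sham 1, and matched WT sham 1 alone at 1.54. A simulated mixture had 0.347, a simulated new draw from the mean of both 0.669 and a simulated independent library 3.81. The first 2 simulations were drawn from the same counts they were compared with, which lowers the index. They set no bound for RNA pooled before sequencing. A mixture and a chance position near the group mean cannot be told apart, since the test of chance decides nothing either. WT sham 4, with an index of 1.30 as a mixture, matched WT sham 2 alone at 1.35. WT TAC 3 and JP2CR TAC 3 matched no single library below 2.19. WT sham 1 matched WT sham 3 at 1.53, and JP2CR sham 1 matched JP2CR sham 2 at 1.64. Whether such close sham libraries are from separate animals was not tested, while the p-values and splits treat the libraries as independent. JP2CR sham 1 and 2 alone make up the JP2CR sham group in the fits without the Xist libraries. No biological explanation was tested.

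The third pattern is the score of genes lower in TAC, which fell less in JP2CR than in WT (0.72, exact permutation p = 0.00122). The 3 libraries with Xist counts do not account for it alone (exact permutation p = 0.00190 without them), nor do genes that track the adipocyte or atrial markers (exact permutation p = 0.00245 without them, difference 0.47). Adipose and atrial tissue taken with the ventricles stays open, since the difference was 0.14 ± 0.11 (SE), within 2 SE of 0, with the marker means as covariates. This setting was chosen after the data were seen, and its prediction was written before its result was seen. Members of the marker lists were not removed from the score, so part of the drop may be built into the fit. The genotype also stays open as a biological explanation, since a covariate that differs between the groups takes up part of any true effect.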

How the results depend on the processing

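The settings without libraries in doubt and with marker means as covariates were chosen after the data were seen; the cause of each move was not tested unless a setting's construction (fewer libraries, a stricter threshold) gives it. The TAC counts in WT and JP2CR stayed within 1.5 times under every other tool, scaling, filter and left-out library, and moved to 1138 higher and 978 lower (WT) and 1147 and 734 (JP2CR) with a fold change of at least 1.5 and to 1442 and 1452 (WT) with the covariates. Interaction counts (12 and 4) were 91 and 41 with DESeq2, 29 and 10 with no filter, 0 and 0 at an adjusted p under 0.01, 2 lower with the fold limit, 213 and 159 without the 3 libraries with Xist, 0 and 0 without the 2 intermediate ones, 42 and 17 without these 5 and 1 and 1 with covariates. Sham genotype counts (0 and 13) were 13 and 39 with DESeq2, 1 higher with upper-quartile factors and 3 and 22 with no filter. They were 2 lower at 0.01, 5 lower with the fold limit and 8 higher with covariates. They were 20 and 44 without the Xist libraries, 0 and 6 without the intermediate ones, and 6 and 16 without these 5. Where 1 direction alone is given here, the other is left out and need not be 0. TAC genotype counts (49 and 39) were 129 and 100 with DESeq2, 95 and 62 with only the groups compared, 3 and 2 at 0.01, 31 and 8 with the fold limit, 228 and 150, 2 and 2, and 14 and 5 in the same library settings, and 18 and 10 with covariates. Replicate numbers did not pair the libraries (1 of 24 correlations of deviations above 0.1, range -0.19 to 0.11); with the number as a replicate block the interaction gave 7 and 2, sham genotype 2 and 20, TAC genotype 47 and 30, TAC in WT 2766 and 2751 and in JP2CR 2770 and 2720, called lists 15, 12, 15, 11 and 17 as without it, and scores 0.03 and 0.72. Called lists (15, 12, 15, 11 and 17) were 0 in all 5 comparisons with an estimated correlation, with all libraries and without the 3, the 2 or the 5 in doubt. With fry they were 19, 13, 0, 0 and 3 in one direction and 25, 24, 2, 2 and 5 in both directions at once. With the preset correlation, TAC genotype gave 9 without the Xist libraries and 8 without 5, counted over the 27 lists tested with all libraries. Without the Xist libraries the B cell and neutrophil markers also had 5 or more tested members. They were called higher in JP2CR TAC than in WT TAC by camera with the preset correlation (adjusted p = 9.14e-06 and 0.00936). With an estimated correlation they were not (adjusted p = 0.346 and 0.396). Reversed in direction were Ucp1 (2.30) and Pck1 (0.0866) in WT TAC with covariates, whose adipocyte mean includes both genes, and 4 lists without the Xist libraries and without 5. Glycolysis in the interaction (adjusted p = 0.998 and 0.918) and unfolded protein genes in sham (0.656 and 0.695) lost their calls, while heat shock (0.000934 and 0.00125) and oxidative stress genes (0.0384 and 0.0429) in sham turned from upward, not called, to called downward with the preset correlation. Leaving out 1 library gave 2502 to 2713 higher and 2485 to 2713 lower (WT TAC), 2434 to 2808 and 2410 to 2721 (JP2CR TAC), 2 to 93 and 0 to 27 (interaction), 0 to 5 and 5 to 27 (sham), 5 to 63 and 3 to 62 (TAC genotype), a score difference of -0.03 to 0.10 (higher) and 0.61 to 0.82 (lower; highest exact permutation p = 0.00449) and a correlation of 0.666 to 0.791. The genes near Jph2 called between the genotypes numbered 1 at each window. At these depths 50.7% of simulated 1.5-fold changes were recovered in the interaction.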

Other observations

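The interaction calls without the 3 libraries with Xist counts were examined after the data were seen, and the genes here were chosen after their values were seen. In that fit of 13 libraries the TAC effect was larger in JP2CR than in WT for Fkbp5 (1.55 ± 0.17 log2 SE, adjusted p = 0.000536), the inflammatory transcription factor gene Cebpb (2.11 ± 0.25, adjusted p = 0.000663), the macrophage receptor gene Cd163 (1.18 ± 0.13, adjusted p = 0.000536) and the circadian deadenylase gene Ccrn4l (1.33 ± 0.15, adjusted p = 0.000663), by edgeR. In the sham hearts of that fit Cebpb was -1.50 ± 0.20 (adjusted p = 0.00309) in JP2CR against WT, while Fkbp5 did not pass (-0.09 ± 0.14, adjusted p = 0.893). Fkbp5 had 51.6 and 38.8 CPM in JP2CR sham 3 and 4, which the fit left out, against 13.3 and 12.9 in JP2CR sham 1 and 2. Its larger TAC effect in JP2CR thus depends on which sham libraries are kept. Without all 5 libraries in doubt, the interaction was 1.54 ± 0.19 for Fkbp5 (adjusted p = 0.0131) and 2.04 ± 0.28 for Cebpb (adjusted p = 0.0152). With all 16 libraries, of these 4 genes only Cd163 was among the 16 called.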
